A study of Mus musculus with 9 samples.

How the data were processed

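RNA was sequenced from HT-22 cells, an immortalized mouse hippocampal cell line, in 3 groups of 3 libraries each: control cells, cells exposed to 2 mM homocysteine thiolactone (HTL) for 24 hours, and cells given 10 mM betaine for 4 hours before the same HTL exposure. HTL is a reactive cyclic thioester formed from homocysteine, and betaine is a methyl donor and osmolyte. Per the labels' protocols, total RNA was extracted with TRIzol and libraries were made with a VAHTS Universal RNA-seq kit. How mRNA was selected, whether the kit kept strand, and what the control cells received are not given in the sources used here. No library of cells given betaine alone was analysed here, so an effect of betaine by itself cannot be separated from its effect on HTL-treated cells.

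The values are FPKM (fragments per kilobase of gene, scaled to the library's mapped fragments) per gene and library, as the authors deposited them, per the file headers. Per the submitters' processing notes, fastp, HISAT2, HTSeq and R 3.2.0 were used with the mouse build mm10. The role and order of these tools, and the options with which reads were counted, are not given in the sources used here. The deposited table lists 21352 genes, each with a symbol, an Entrez identifier and GO terms. Reads that fit near-identical gene copies, or overlapping and antisense genes, may have been dropped or split, so values of such genes are uncertain.

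FPKM keeps the depth where whole reads were counted. Library totals were inferred from the steps of low values, such that gene lengths came out whole. Each gene's length was then the shortest that gave whole reads in every library. These inferred lengths, not annotated ones, were also used wherever length is read below. The reads on listed genes came out at 38965175, 34686047 and 39452715 for control replicates 1 to 3, at 39436252, 37505825 and 38255531 for HTL, and at 39262163, 35872353 and 33295131 for betaine plus HTL. They made up 99.97% of the total that each library's FPKM had been scaled to. With those totals the FPKM of 21352 of 21352 genes gave whole reads in every library, within a tolerance of 0.05 reads. Since each length was chosen to give whole reads, and few reads are easily fitted, this count is a weak check. On simulated libraries 99.851% of 2015 genes with at least 20 reads in a library were recovered exactly.

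Genes with a mean of at least 0.5 FPKM over the 9 libraries were kept, which left 11012. They were tested on log2(FPKM + 1) with limma 3.58.1 in R 4.3.3, with group means, an intensity trend and 1 shared estimate of the spread (6 residual degrees of freedom). A fold change on this scale understates the change of genes with low values. Tests were two-sided, with Benjamini-Hochberg adjustment within each of the 3 comparisons and a threshold of 0.05. A single gene cannot reach that threshold in an exact permutation test of 3 libraries against 3, whose smallest p is 0.1. Nothing in the labels says that the libraries of a group came from separate cultures, so p-values measure only the spread between these libraries, which may be technical. Replicates within a group differed beyond counting noise, with chi-square per degree of freedom from 2.85 to 6.15 over genes with at least 20 reads, so no library was a copy of another.

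Of 35 gene lists fixed before the data were examined, 31 had at least 5 measured members. They were tested with limma's camera at a preset correlation of 0.01, which compares a list with all other genes, adjusted over the lists of a comparison. Camera with an estimated correlation and fry were run beside it. The estimated form also rests on the 6 residual degrees of freedom, so its p is larger even where the correlation is no higher. For the NRF2 list in HTL against control the estimate was 0.01, yet camera's unadjusted p went from 0.000278 to 0.011. A list lost with an estimated correlation is thus not shown to have correlated members. Lists can share members, so their results are not independent. Hmox1 is in the NRF2 and the ferroptosis lists, and Slc7a11 in the transsulfuration, ATF4 and NRF2 lists. Genes named in the text follow a rule that was also fixed beforehand. It takes, per comparison, the 8 largest rises and the 8 largest falls among genes past the threshold with at least 1 FPKM in the higher group and no overlap between the libraries of the groups compared. It leaves out provisional symbols (Gm with digits, or ending in Rik) and rows without a symbol. It adds the 3 members with the smallest p of each list past the threshold, and 16 genes of homocysteine metabolism and stress responses in every comparison. Some genes that the rule takes are not reported here. Other genes named as members of a list, of a GO term or of the mitochondrial transcripts were chosen after their values were seen.

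Gene positions were matched by Entrez identifier to the RefSeq annotation of GRCm38 for 20699 genes, and GC content came from GENCODE transcripts for 17640. The test was tried on simulated counts with 50 genes changed at each of 4 sizes in HTL against control, of 10907 tested. It recovered 6% of genes changed 1.1-fold, 74% at 1.2-fold, 98% at 1.5-fold and 100% at 2-fold, and 5.23% of the calls were unchanged genes.

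The alternatives fixed beforehand were pseudocounts of 0.1 and 5, no filter, a filter at 5 FPKM, quantile normalization, TPM, median-of-ratios size factors, the replicate number as a block, each library left out, the 6 libraries of a comparison alone, a robust fit without the trend, and a log2 fold change of at least 1 as well. A voom fit on the recovered reads and a pair of GC and length corrections were added after the data were seen. Python 3.11.15 with matplotlib 3.10.9 drew the plots.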

Results

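The data are the transcriptomes of 9 libraries of HT-22 cells, with 3 control, 3 HTL and 3 betaine plus HTL libraries. Reads on listed genes ranged from 33295131 to 39452715 per library, and 16441 to 17256 genes lay above 0 FPKM in a library. The 10 most abundant genes held 8.8% to 9.67% of a library's FPKM. Libraries of a group correlated at r = 0.9979 to 0.9985 across genes, against 0.9895 to 0.9899 between control and HTL, 0.9939 to 0.9951 between HTL and betaine plus HTL, and 0.9859 to 0.9872 between control and betaine plus HTL. The first principal component held 64% of the variance and the second 18.8%.

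Markers of cell types were read as levels. Of 43 neuronal and synaptic genes, 12 had a mean of at least 0.5 FPKM, the highest being Vamp2 at 26.4 FPKM. Mapt and Map2 reached at most 0.02 and 0.41 FPKM in a library. Of 10 astrocyte markers 2 had a mean of at least 0.5 FPKM, with the gap junction gene Gja1 at 125 FPKM, while Gfap reached at most 0.03 FPKM in a library. That mean was reached by 3 of 12 microglial markers (highest Tmem119, 7.43 FPKM), 2 of 10 oligodendrocyte markers (Cspg4, 6.72 FPKM) and 1 of 9 endothelial markers (Flt1, 2.73 FPKM). It was reached by 5 of 12 fibroblast and mesenchymal markers, with the intermediate filament gene Vim at 883 FPKM, while Lum reached at most 0.01 FPKM in a library.

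HTL against control asks what the thiolactone changed. Genes of cholesterol synthesis fell together. Of 25 measured members, 24 fell and 1 rose, with a median log2 fold change of -0.90. Hmgcs1, which makes the precursor of mevalonate (chromosome 13, 119690351 to 119708260, GRCm38), went from 86.7 ± 1.22 to 35.8 ± 0.79 FPKM (SD, n = 3 each). Nsdhl, a sterol dehydrogenase of the same pathway, went from 37.1 ± 0.91 to 12.9 ± 0.42 FPKM. The acute-phase gene Saa3 rose from 491 ± 12.1 to 1681 ± 16.4 FPKM.

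The cholesterol list passed camera at an adjusted p of 1.12e-22, and at 0.000883 with an estimated correlation. The counts were 24 falls and 1 rise adjusted over the list alone as well. Msmo1 fell from 128 to 59.98 FPKM (log2 fold change -1.09) and Lss, which closes the sterol rings, from 22.9 to 8.61 FPKM (-1.32). The member that rose was Ggps1, which makes the geranylgeranyl precursor, from 5.19 to 5.71 FPKM. Fatty acid synthesis genes fell in 18 of 19 members, by the count over all genes and adjusted over the list alone, and 1 rose. Their median was -0.53, with an adjusted p of 3.63e-12 by camera, and 0.00935 with an estimated correlation. The desaturase Scd2 went from 648 ± 10.4 to 385 ± 2.44 FPKM, Scd1 from 131 to 72.7 FPKM and Fads2 from 128 to 78.9 FPKM.

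**Figure D1:**
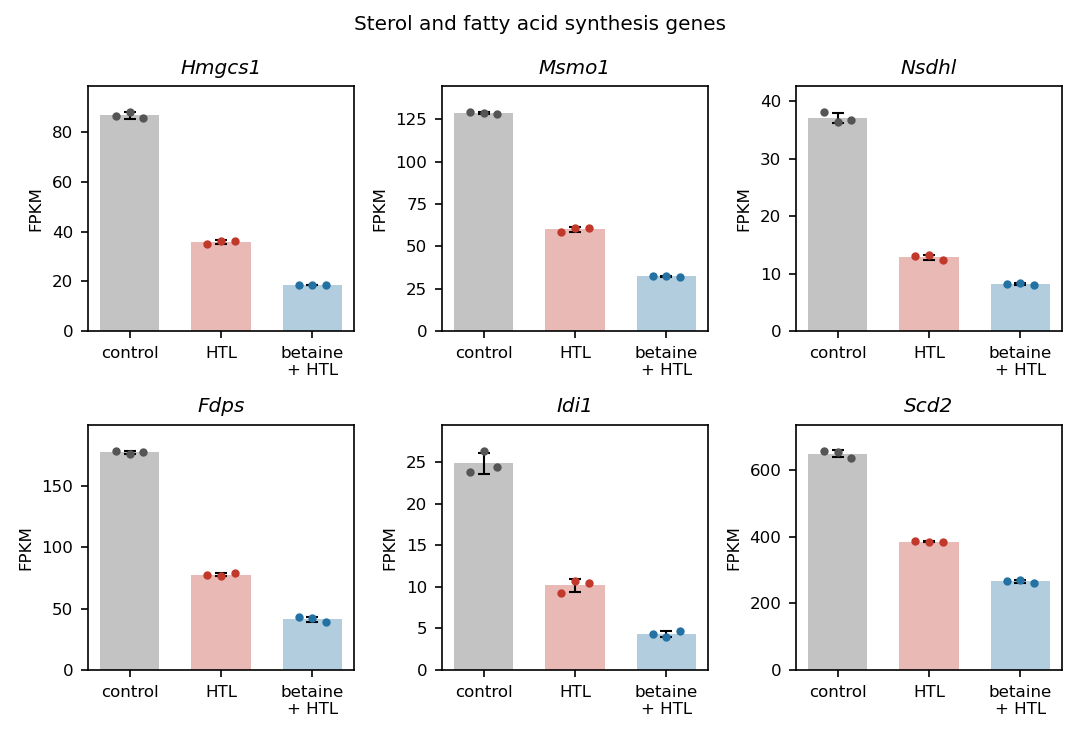
FPKM (y axis, from 0) of 6 sterol and fatty acid synthesis genes in control, HTL and betaine plus HTL cells. Points are the 3 libraries of a group, bars their mean and error bars the SD; Hmgcs1 averaged 86.7, 35.8 and 18.6 FPKM in this order.

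Among other large rises in HTL cells were Fas, a death receptor gene, from 18.5 ± 0.43 to 48.4 ± 0.42 FPKM (log2 fold change 1.34 ± 0.03 SE, limma adjusted p = 9.57e-11), and the chemokine gene Cxcl12 from 17.2 to 44.9 FPKM. Txnip, which encodes a thioredoxin-binding protein, rose from 4.35 to 13.3 FPKM, Fmo1 from 6.30 to 18.6 FPKM, Anxa8 from 11.4 to 32.2 FPKM and Chil1 from 3.14 to 10.3 FPKM. Car6, a secreted carbonic anhydrase, rose from 0.15 to 1.88 FPKM. Angptl2 fell from 13.8 ± 0.64 to 2.16 ± 0.20 FPKM. Sprr1a and Cdsn, known from the cornified skin layer, fell from 75.3 to 23.9 and from 25.04 to 7.91 FPKM. The chemokine gene Ccl5 fell from 135 to 50.8 FPKM and the glutamine transporter gene Slc1a5 from 30.9 to 11.7 FPKM. Tmem238 fell from 4.15 to 0.72 FPKM. Saa3 belongs to a family of related genes, so its level is uncertain if reads were shared.

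Of the methionine cycle and one-carbon list, 13 members fell and 5 rose of 26, also when adjusted over the list alone (median -0.09, camera adjusted p = 0.000986, and 0.0345 with an estimated correlation). Ahcy, which hydrolyses S-adenosylhomocysteine, fell from 91.1 ± 2.72 to 71.6 ± 1.49 FPKM and Mat2a, which makes S-adenosylmethionine, from 88.4 to 72.2 FPKM. Mthfd1l fell from 49.5 to 36.7 FPKM and Gart from 35.7 to 26.5 FPKM, while Mtr, methionine synthase, rose from 3.86 to 5.22 FPKM. Blmh, whose product hydrolyses HTL, rose from 42.7 to 48.0 FPKM. Cth, of transsulfuration, rose from 18.3 to 20.1 FPKM, and this call was lost under size factors (adjusted p = 0.384) and without control replicate 3 (0.0869) or HTL replicate 2 (0.0726), with 0.00499 to 0.384 over all settings. Cbs, Bhmt and the betaine transporter gene Slc6a12 were too low to test, with at most 0.058, 0.013 and 0.008 FPKM in a library.

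NRF2 targets fell in 15 members and rose in 8 of 31, also when adjusted over the list alone (median -0.11, and -0.06 without HTL replicate 1, camera adjusted p = 0.000986, and 0.0486 with an estimated correlation). Hmox1, heme oxygenase, fell from 252 ± 2.64 to 160 ± 1.47 FPKM, Nqo1 from 37.4 to 23.9 FPKM and Srxn1 from 39.2 to 24.7 FPKM. Heat shock genes fell in 15 members and rose in 3 of 22 (16 and 3 adjusted over the list alone, median -0.18, camera adjusted p = 1.43e-05, and 0.0312 with an estimated correlation). Among them the chaperonin gene Hspd1 went from 611 to 470 FPKM, with Hsp90aa1 at 368 and 303 FPKM and Hsph1 at 59.4 and 46.9 FPKM. Interferon response genes fell in 17 and rose in 6 of 31 (19 and 6 adjusted over the list alone, median -0.16, camera adjusted p = 0.000524, and 0.0312 with an estimated correlation). Oas3 fell from 1.36 to 0.38 FPKM and Ifit3 from 4.07 to 2.16 FPKM, while Gbp2 rose from 24.0 to 34.8 FPKM. The interferon call was lost with the filter at 5 FPKM (adjusted p = 0.0786, with 5.65e-05 to 0.0786 over all settings). Ribosome biogenesis and MYC genes fell in 25 and rose in 3 of 37, also when adjusted over the list alone (median -0.19, camera adjusted p = 6.09e-10, and 0.0312 with an estimated correlation), with Nop56 at 51.7 and 37.2 FPKM, Srm at 168 and 129 FPKM and Ddx21 at 116 and 90.0 FPKM.

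The other 6 called lists of HTL against control were lost with an estimated correlation. The estimate was above the preset 0.01 for each but ferroptosis and iron genes (0.005). Mitosis and G2/M genes rose in 32 and fell in 2 of 45 (33 and 2 adjusted over the list alone, camera adjusted p = 5.17e-05, and adjusted p = 0.169 with an estimated correlation). Cenpf rose from 11.6 to 19.3 FPKM, the proliferation marker gene Mki67 from 50.8 to 65.8 FPKM and Kif11 from 46.7 to 57.9 FPKM. Ribosomal protein genes fell in 32 of 47 (34 adjusted over the list alone) and none rose (camera adjusted p = 2.97e-10, and adjusted p = 0.235 with an estimated correlation), with Rpsa at 1049 and 881 FPKM. Extracellular matrix genes fell in 17 and rose in 10 of 29, also when adjusted over the list alone (camera adjusted p = 0.00152, and adjusted p = 0.221 with an estimated correlation). Timp2, a metalloproteinase inhibitor gene, fell from 161 to 72.6 FPKM and Col6a1 from 32.9 to 17.1 FPKM. Endoplasmic reticulum (ER) chaperone and unfolded protein response genes rose in 16 and fell in 2 of 26 (17 and 2 adjusted over the list alone, camera adjusted p = 0.031, and adjusted p = 0.221 with an estimated correlation). Hspa5, the main ER chaperone, rose from 328 ± 3.01 to 453 ± 4.20 FPKM and Ero1b from 1.94 to 3.74 FPKM, while Dnajb11 fell from 28.5 to 19.6 FPKM. The ER call was lost under size factors (adjusted p = 0.134) and without HTL replicate 2 (0.0593), with 0.000612 to 0.134 over all settings.

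Ferroptosis and iron genes (10 fell and 8 rose of 23, also when adjusted over the list alone) and nuclear oxidative phosphorylation genes (15 fell and 8 rose of 52, 14 and 8 adjusted over the list alone) both had a camera adjusted p of 0.047. With an estimated correlation the adjusted p was 0.169 and 0.698. Chac1 fell from 46.8 to 25.2 FPKM, and Ndufb10 from 175 to 136 FPKM. The oxidative phosphorylation call was lost under quantile normalization (adjusted p = 0.996), where its median turned to 0.01, without control replicate 3 (0.162), HTL replicate 2 (0.096) or 3 (0.0501), and betaine plus HTL replicate 1 (0.0666) or 3 (0.0509), in 12 of 21 settings in all, with 0.00366 to 0.996. The ferroptosis call was lost in 9 of 21 settings, among them without control replicate 1 (adjusted p = 0.0696), HTL replicate 2 (0.0509) or betaine plus HTL replicate 3 (0.0522), with 0.0372 to 0.105 over all. The other 18 lists had adjusted p from 0.0574 to 0.976. The lowest was that of autophagy and lysosome genes, of which 25 rose and 6 fell of 40 (median 0.16, camera adjusted p = 0.0574). Over all settings it ran from 0.00274 to 0.0921. In the list of ATF4 and integrated stress response genes 14 fell and 12 rose of 40 (14 and 13 adjusted over the list alone, adjusted p = 0.475). Ddit3, a stress transcription factor gene, was at 16.3 and 15.5 FPKM (limma adjusted p = 0.29, and 0.0291 to 0.783 over all settings), Atf4 at 496 and 519 FPKM (0.054, and 0.000545 to 0.511 over all settings), Slc7a11 at 11.3 and 11.5 FPKM (0.649) and Cdkn1a at 13.5 and 14.3 FPKM (0.154, and 0.0349 without HTL replicate 1, with 0.0349 to 0.942 over all settings). Trib3 fell from 66.9 to 54.7 FPKM.

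In all, limma called 6639 of 11012 genes in HTL against control, of which 4388 rose and 2251 fell. At least 2-fold changes were seen for 19 rises and 31 falls, and the median size of a called change was 0.24 on the log2 scale. The libraries of the groups did not overlap for 67.2% of genes, where chance gives 10%. The share of calls that rose was 66.1%, against 52.2% under quantile normalization and 46.5% under size factors.

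Betaine plus HTL against HTL asks what the pretreatment changed in cells under HTL. Cholesterol synthesis genes fell again, in 24 of 25 members, with a median of -0.60. Interferon response genes rose in 25 of 31 members and none fell, with a median of 0.33. Genes of the integrated stress response, which ATF4 drives, rose in 32 of 40 and fell in 1. Ifit1, an antiviral gene, went from 26.6 ± 0.46 to 48.1 ± 0.80 FPKM, and Slc7a11, the cystine importer gene, from 11.5 ± 0.18 to 18.4 ± 0.25 FPKM (SD, n = 3 each).

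Adjusted over the list alone, cholesterol genes fell in 24 members, interferon genes rose in 26, and integrated stress response genes rose in 32 and fell in 2. Camera gave these lists an adjusted p of 4.04e-21, 2.89e-17 and 3.28e-17, and 0.000661 for each with an estimated correlation. Idi1 fell from 10.2 to 4.36 FPKM, Insig1, a sterol sensor gene, from 23.9 to 11.1 FPKM, Hmgcs1 from 35.8 to 18.6 FPKM, Fdps from 77.8 to 41.4 FPKM and Cyp51 from 33.3 to 17.6 FPKM. The cholesterol gene that did not pass was Ggps1, at 5.71 and 5.56 FPKM. Fatty acid synthesis genes fell in 12 of 19, also when adjusted over the list alone, and none rose (camera adjusted p = 1.65e-06, and 0.0143 with an estimated correlation), with Scd2 at 385 and 266 FPKM. Rsad2, an antiviral gene, rose from 3.32 to 7.40 FPKM, Ifit3 from 2.16 to 5.22 FPKM and Gbp2 from 34.8 to 58.3 FPKM.

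**Figure D2:**
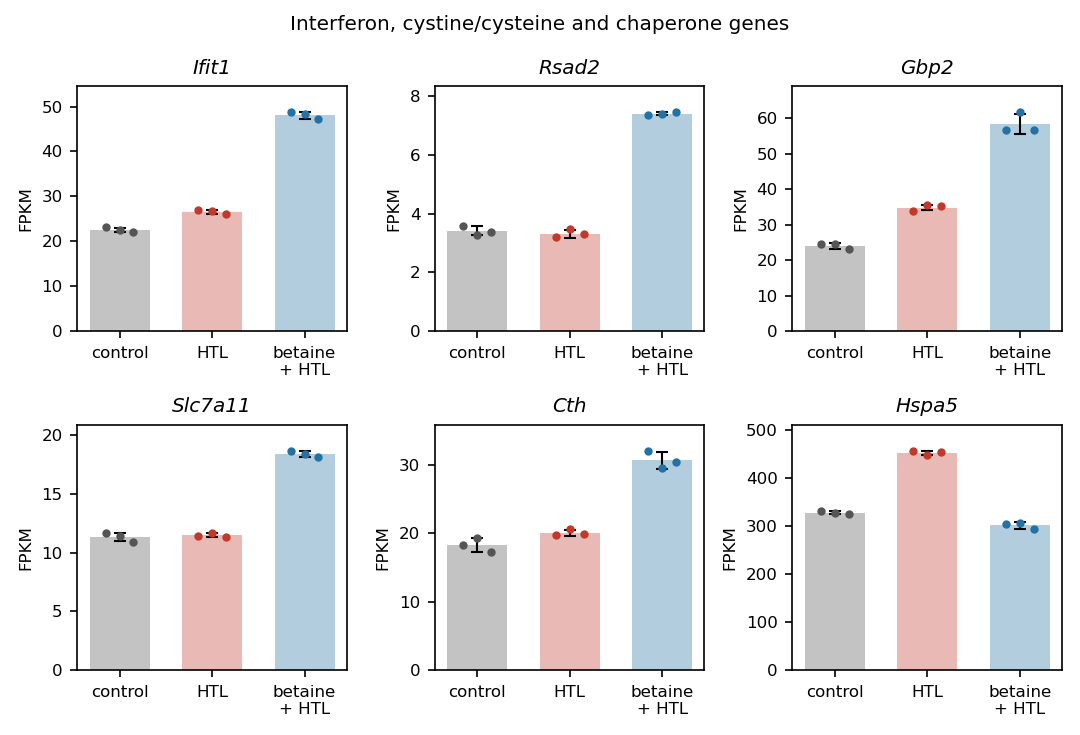
FPKM (y axis, from 0) of 3 interferon response genes, the cystine importer gene Slc7a11, Cth and the ER chaperone gene Hspa5 in the 3 groups. Points are libraries, bars means and error bars the SD over 3 libraries; Hspa5 averaged 328, 453 and 302 FPKM in control, HTL and betaine plus HTL cells.

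NF-kB and inflammatory genes rose in 18 and fell in 2 of 26 (18 and 3 adjusted over the list alone, median 0.22, camera adjusted p = 1.34e-08, and 0.00539 with an estimated correlation). The cyclooxygenase gene Ptgs2 rose from 26.9 ± 0.39 to 61.2 ± 1.26 FPKM (log2 fold change 1.16 ± 0.03 SE, limma adjusted p = 9.75e-10), Ccl5 from 50.8 to 98.4 FPKM and Cxcl10 from 105 to 163 FPKM. Of the stress response list, the glycine transporter gene Slc6a9 rose from 37.7 to 52.9 FPKM and Aldh1l2 from 37.7 to 50.5 FPKM. Atf4 itself rose from 519 to 598 FPKM and Trib3 from 54.7 to 64.2 FPKM, while Ddit3 fell from 15.5 to 11.8 FPKM. ER chaperone genes fell in 17 and rose in 1 of 26, also when adjusted over the list alone (median -0.15, camera adjusted p = 5.92e-06, and 0.0255 with an estimated correlation). Hspa5 fell from 453 to 302 FPKM, Sdf2l1 from 22.2 to 12.9 FPKM and Calr from 595 to 459 FPKM.

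DNA replication and G1/S genes fell in 30 and rose in 2 of 43 (33 and 2 adjusted over the list alone, median -0.17, camera adjusted p = 4.24e-08, and 0.00353 with an estimated correlation). Cdc6 fell from 22.5 to 16.0 FPKM and Tyms, thymidylate synthase, from 17.9 to 13.7 FPKM, while Rrm2 rose from 81.0 to 102 FPKM. NRF2 targets rose in 17 and fell in 4 of 31 (18 and 5 adjusted over the list alone, camera adjusted p = 1.65e-06, and 0.00988 with an estimated correlation), with Gsta4 at 120 and 199 FPKM and Nqo1 at 23.9 and 33.2 FPKM. Hmox1 rose from 160 to 191 FPKM. Hypoxia and glycolysis genes rose in 18 and fell in 2 of 30 (18 and 3 adjusted over the list alone, camera adjusted p = 5.92e-06, and 0.00832 with an estimated correlation), among them Vegfa from 31.7 to 50.7 FPKM and the glucose transporter gene Slc2a1 from 56.3 to 72.6 FPKM. Genes known as p53 targets rose in 13 and fell in 2 of 35, also when adjusted over the list alone (camera adjusted p = 0.000309, and 0.0143 with an estimated correlation), with Plk2 at 79.9 and 108 FPKM and Sesn2 at 20.7 and 27.5 FPKM. Cdkn1a rose from 14.3 to 16.7 FPKM. TGF-beta targets rose in 7 and fell in 1 of 19 (8 and 3 adjusted over the list alone, camera adjusted p = 0.00304, and 0.0429 with an estimated correlation), with the actin gene Acta2 at 20.1 and 43.6 FPKM and Pmepa1 at 3.04 and 5.62 FPKM.

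Prl2c2, a gene of the prolactin family, rose from 115 ± 2.72 to 324 ± 12.7 FPKM. It is uncertain, since its near copy Prl2c3 stood at 16.4 FPKM in control replicate 3 and at most 1.67 FPKM in the other libraries. Gsta1 was called at 0.82 and 2.96 FPKM, where betaine plus HTL replicate 3 alone stood at 5.89 FPKM and its log2 fold change went from 0.96 to 0.46 without that library, and the call was lost without HTL replicate 1 (adjusted p = 0.12), HTL replicate 3 (0.0882) or control replicate 2 (0.0503), with 0.0048 to 0.162 over all settings. Lce1g rose from 5.47 to 10.8 FPKM. Car6 fell from 1.88 to 0.22 FPKM, Hp, haptoglobin, from 1.42 to 0.25 FPKM, and Egr1, an immediate early gene, from 3.80 to 1.496 FPKM. Of the methionine cycle genes, Ahcy was at 71.6 and 70.0 FPKM (limma adjusted p = 0.424) and Mtr at 5.22 and 5.64 FPKM (0.252), and Mat2a fell from 72.2 to 64.2 FPKM. Blmh fell from 48.0 to 40.6 FPKM.

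In this comparison 6 lists were called and lost with an estimated correlation. The estimate was above the preset 0.01 for each but the transsulfuration list (-0.018). Transsulfuration and glutathione synthesis genes rose in 7 and fell in 2 of 17, also when adjusted over the list alone (camera adjusted p = 0.047, and adjusted p = 0.137 with an estimated correlation), with Cth from 20.1 to 30.7 FPKM and Gclc from 34.9 to 46.9 FPKM. That call was lost in 11 of 21 settings (adjusted p = 0.0191 to 0.0824), among them without HTL replicate 2 (0.0824, with a median of -0.03), control replicate 1 (0.054) or 2 (0.0511), and betaine plus HTL replicate 1 (0.0737) or 3 (0.0774, with a median of -0.02). Antioxidant enzyme genes fell in 7 and rose in 2 of 19 (8 and 2 adjusted over the list alone, camera adjusted p = 0.0258, and adjusted p = 0.24 with an estimated correlation), with Sod2 from 72.8 to 58.4 FPKM, and the call was lost without betaine plus HTL replicate 3 (adjusted p = 0.0779, with 0.00769 to 0.235 over all settings). Mitosis and G2/M genes rose in 14 and fell in 4 of 45, also when adjusted over the list alone (camera adjusted p = 0.0168, and adjusted p = 0.413 with an estimated correlation), a call lost without betaine plus HTL replicate 2 (adjusted p = 0.0531, with 0.001 to 0.0531 over all settings). Ribosome biogenesis and MYC genes rose in 10 and fell in 3 of 37, also when adjusted over the list alone (camera adjusted p = 0.0284, and adjusted p = 0.334 with an estimated correlation), with Myc from 65.6 to 90.0 FPKM, a call lost without betaine plus HTL replicate 1 (adjusted p = 0.0737, with 0.00411 to 0.0737 over all settings) or HTL replicate 2 (0.0525). Ribosomal protein genes rose in 15 of 47, also when adjusted over the list alone, and none fell (camera adjusted p = 0.000309, and adjusted p = 0.485 with an estimated correlation), a call lost under quantile normalization (adjusted p = 0.123, with 6.89e-12 to 0.123 over all settings) and without betaine plus HTL replicate 1 (0.0737). Nuclear oxidative phosphorylation genes fell in 18 of 52, also when adjusted over the list alone, and none rose (camera adjusted p = 0.00044, and adjusted p = 0.485 with an estimated correlation), with Ndufa5 from 71.9 to 52.7 FPKM, a call lost under both GC and length corrections (adjusted p = 0.702 and 0.395, with 7.79e-07 to 0.702 over all settings). The other 14 lists had adjusted p from 0.133 to 0.932.

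In all, 3871 of 11012 genes were called in betaine plus HTL against HTL, with 1601 rises and 2270 falls, of which 3 and 3 were at least 2-fold. The median size of a called change was 0.19 on the log2 scale, and groups did not overlap for 47.7% of genes, where chance gives 10%. The share that rose was 41.4%, against 51.8% under quantile normalization and 55.3% under size factors.

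Betaine plus HTL against control asks how far pretreated cells still differed from untreated ones. Cholesterol synthesis genes fell in 24 of 25 members, with a median of -1.47. Idi1 was at 24.9 ± 1.29 FPKM in control and 4.36 ± 0.35 FPKM in betaine plus HTL cells, and Hmgcs1 at 86.7 ± 1.22 and 18.6 ± 0.03 FPKM (SD, n = 3 each). Of 26 NF-kB and inflammatory genes 16 rose and 4 fell, a list that passed camera but had an adjusted p = 0.0913 with an estimated correlation. Among them the chemokine gene Ccl2 rose from 969 ± 9.38 to 2042 ± 28.8 FPKM. Fas was at 18.5 and 59.8 FPKM.

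The cholesterol count was the same adjusted over the list alone, with a camera adjusted p of 7.06e-23, and 0.000861 with an estimated correlation. Fdps fell from 177 to 41.4 FPKM, Insig1 from 55.1 to 11.1 FPKM, Nsdhl from 37.1 to 8.17 FPKM, Lss from 22.9 to 4.85 FPKM and Msmo1 from 128 to 32.3 FPKM. Fatty acid synthesis genes fell in 18 of 19, also when adjusted over the list alone, and none rose (median -0.66, camera adjusted p = 4.66e-13, and 0.00769 with an estimated correlation). Integrated stress response genes rose in 26 and fell in 6 of 40, also when adjusted over the list alone (median 0.21, camera adjusted p = 0.00037, and 0.0284 with an estimated correlation), with asparagine synthetase, Asns, from 98.5 to 147 FPKM and Slc6a9 from 33.9 to 52.9 FPKM. DNA replication and G1/S genes fell in 24 and rose in 6 of 43, also when adjusted over the list alone (median -0.16, camera adjusted p = 1.69e-05, and 0.0137 with an estimated correlation), with Ccne1, cyclin E1, from 13.2 to 7.70 FPKM. These 4 lists held with an estimated correlation, of 13 called.

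The other 9 were lost with it. The estimate was under the preset 0.01 for NF-kB (0.008), interferon (0.001) and autophagy genes (-0.001), and above it for the others. NF-kB and inflammatory genes rose in 16 and fell in 4 of 26, also when adjusted over the list alone (camera adjusted p = 0.00647, and adjusted p = 0.0913 with an estimated correlation), with Cxcl10 from 75.7 to 163 FPKM and Cxcl1 from 219 to 372 FPKM. Interferon response genes rose in 16 and fell in 5 of 31, also when adjusted over the list alone, with a camera adjusted p of 0.05 that lay just under the threshold, and adjusted p = 0.129 with an estimated correlation. That call was lost with TPM (adjusted p = 0.0512) and without control replicate 1 (0.0676), betaine plus HTL replicate 1 (0.0619) or HTL replicate 3 (0.0532), with 0.00604 to 0.0676 over all settings. Mitosis and G2/M genes rose in 33 and fell in 3 of 45 (36 and 3 adjusted over the list alone, camera adjusted p = 4.21e-06, and adjusted p = 0.117 with an estimated correlation), with Cdc25b from 58.3 to 84.8 FPKM. Autophagy and lysosome genes rose in 26 and fell in 8 of 40 (27 and 9 adjusted over the list alone, camera adjusted p = 0.0157, and adjusted p = 0.0913 with an estimated correlation). Nbr1, an autophagy receptor gene, rose from 26.8 to 38.4 FPKM, while Lamp1 fell from 295 to 132 FPKM and Ctsb from 186 to 134 FPKM, both encoding lysosomal proteins. Extracellular matrix genes fell in 17 and rose in 5 of 29 (18 and 5 adjusted over the list alone, camera adjusted p = 0.000477, and adjusted p = 0.161 with an estimated correlation), with Spp1 from 657 to 397 FPKM. The autophagy list was not particular to pretreated cells. Its counts were close in HTL against control (25 rose and 6 fell), while 10 rose and 10 fell in betaine plus HTL against HTL.

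Heat shock genes fell in 14 and rose in 4 of 22 (14 and 5 adjusted over the list alone, camera adjusted p = 0.00362, and adjusted p = 0.0913 with an estimated correlation), with Hsp90aa1 from 368 to 283 FPKM. Ribosome biogenesis and MYC genes fell in 23 and rose in 5 of 37, also when adjusted over the list alone (camera adjusted p = 4.48e-05, and adjusted p = 0.0913 with an estimated correlation), with Srm from 168 to 130 FPKM. Ribosomal protein genes fell in 23 and rose in 4 of 47, also when adjusted over the list alone (camera adjusted p = 0.00037, and adjusted p = 0.483 with an estimated correlation), a call lost under quantile normalization (adjusted p = 0.468, with 2.11e-06 to 0.514 over all settings). Nuclear oxidative phosphorylation genes fell in 24 and rose in 4 of 52 (23 and 4 adjusted over the list alone, camera adjusted p = 6.73e-05, and adjusted p = 0.453 with an estimated correlation), with Ndufb10 from 175 to 116 FPKM, a call lost under quantile normalization (adjusted p = 0.0747, with 1.55e-06 to 0.227 over all settings). The other 18 lists had adjusted p from 0.0634 to 0.777.

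Among single genes against control, Prl2c2 rose from 81.3 to 324 FPKM, with the same uncertainty as above, Pmepa1 from 1.33 to 5.62 FPKM, Klhl24 from 2.32 to 8.16 FPKM and Anxa8 from 11.4 to 31.3 FPKM. Krt16 rose from 0.43 to 2.53 FPKM, Enpp2, which makes autotaxin, from 0.47 to 2.49 FPKM, and Gbp2 from 24.0 to 58.3 FPKM. Egr1 fell from 7.98 to 1.496 FPKM. Cth rose from 18.3 ± 0.98 to 30.7 ± 1.26 FPKM, Slc7a11 from 11.3 to 18.4 FPKM, Mtr from 3.86 to 5.64 FPKM and Cdkn1a from 13.5 to 16.7 FPKM. Ahcy fell from 91.1 to 70.0 FPKM, Mat2a from 88.4 to 64.2 FPKM, Hmox1 from 252 to 191 FPKM, Ddit3 from 16.3 to 11.8 FPKM and Hspa5 from 328 to 302 FPKM. Blmh was called at 42.7 and 40.6 FPKM (limma adjusted p = 0.0461), a call lost in 16 of 21 settings, with an adjusted p from 0.00257 to 0.533 over them. Trib3 was at 66.9 and 64.2 FPKM (adjusted p = 0.202, and 0.00994 without betaine plus HTL replicate 3, with 0.00994 to 0.657 over all settings).

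In all, 6981 of 11012 genes were called in betaine plus HTL against control, with 4151 rises and 2830 falls, of which 35 and 54 were at least 2-fold. The median size of a called change was 0.25 on the log2 scale, and groups did not overlap for 67.1% of genes, where chance gives 10%. The share that rose was 59.5%, against 52.4% under quantile normalization and 48.2% under size factors.

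**Figure D3:**
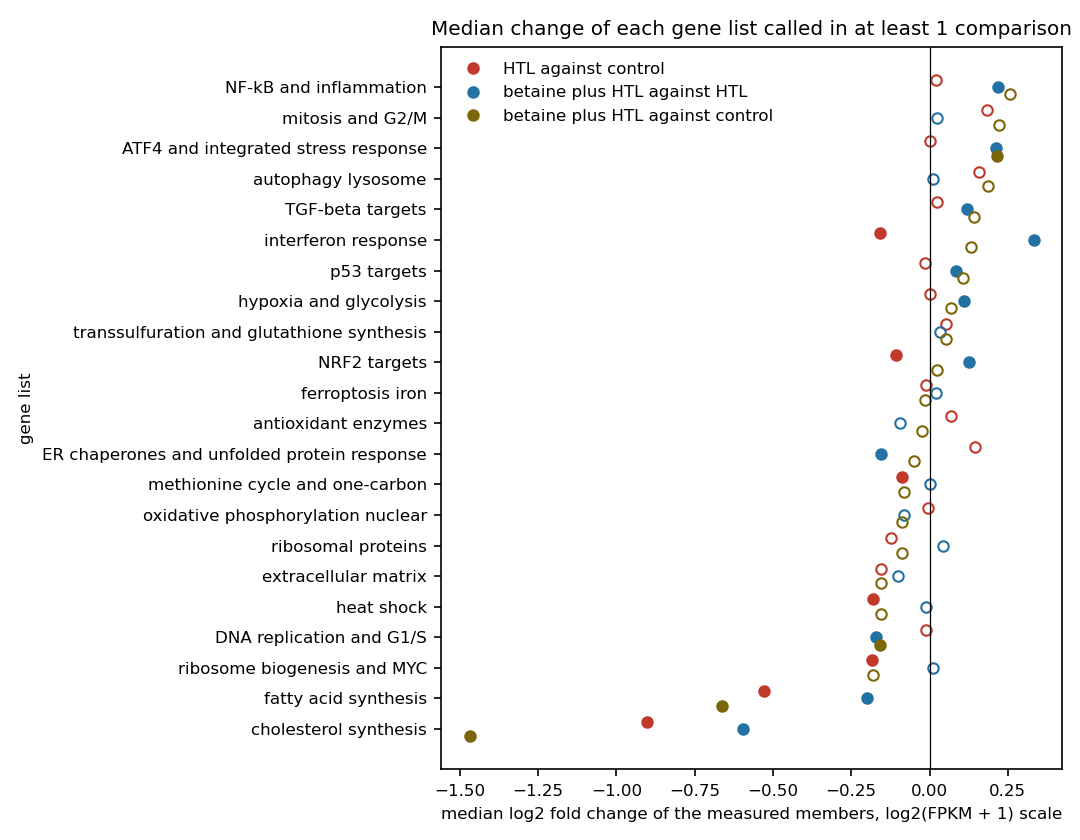
Median log2 fold change (x axis) of the measured members of each gene list (y axis) called in at least 1 comparison, coloured by comparison. Filled points have an adjusted p under 0.05 with an estimated correlation, open points do not; cholesterol synthesis lies at -0.90, -0.60 and -1.47.

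In the called lists of the 3 comparisons the median, the mean and the camera direction had the same sign. In 8, 5 and 4 of the lists that were not called they differed. By fry, which asks only whether a list moves on balance, 12 of 13, 16 of 17 and 13 of 13 called lists passed. Lists that were not called could pass fry too. In HTL against control apoptosis regulators (fry adjusted p = 5.45e-05) and NF-kB genes (0.00016) did, while DNA replication and G1/S genes (0.654) did not. Passing fry thus does not set the called lists apart.

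Whether the pretreatment moved genes against the HTL change was read from genes called in both HTL against control and betaine plus HTL against HTL. Of 2532 such genes, 1504 changed in opposite directions and 1028 in the same direction. Saa3 is among the first, at 491, 1681 and 977 FPKM in control, HTL and betaine plus HTL cells, as are Cxcl12 at 17.2, 44.9 and 27.1 FPKM and Hspa5. Hmgcs1 and Fas are among the second. Of the opposite changes 994 rose with HTL and then fell, where independent lists would share 905, and 510 fell and then rose, against 327. In the same direction 546 genes rose, against 638 for independent lists, and 482 fell, against 464.

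Both comparisons use the HTL libraries, with opposite signs, so a negative covariance arises without any effect. Across genes, which are not independent replicates, the covariance of the log2 fold changes was -0.0044, against -0.0017 on average in 100 simulations without an effect, a difference of -0.0027. The correlation was -0.10, against -0.50 in the simulations. On average these gave 0.01 opposite calls and 0.01 genes called in both comparisons. They hold no HTL effect, so hardly a gene could be called. Neither their counts nor their correlation is thus a reference for the 1504 opposite changes or the -0.10. With 3 HTL libraries no split leaves 2 in each part, and part of the excess may come from the shared libraries.

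**Figure D4:**
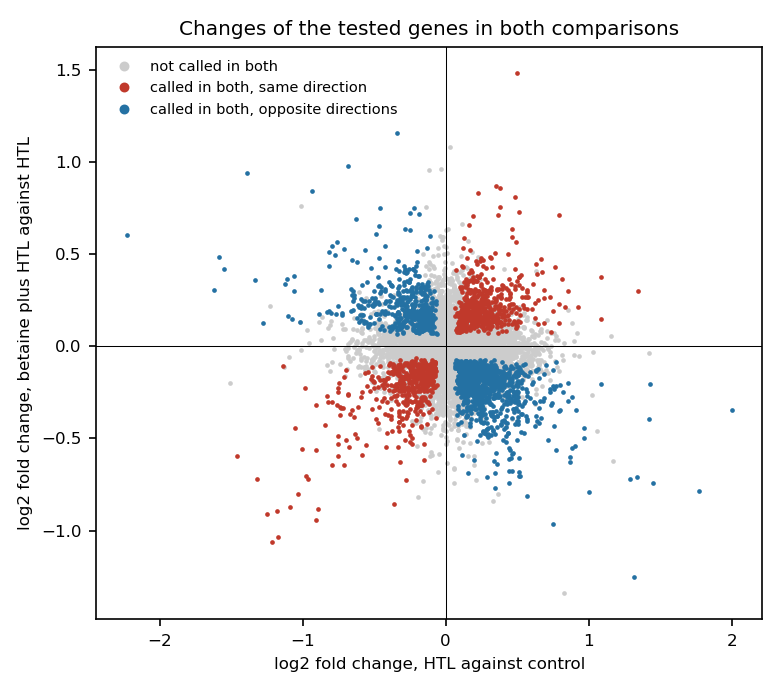
Log2 fold change of each of 11012 genes in HTL against control (x axis) and in betaine plus HTL against HTL (y axis). Each point is a gene: 1504 called in both with opposite directions (blue), 1028 in the same direction (red), the rest grey.

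On a scale where control is 0 and HTL is 1, the median position of betaine plus HTL was 0.864 ± 0.033 (SD over 3 betaine plus HTL libraries) for the 4388 genes that rose with HTL and 0.993 ± 0.008 for the 2251 that fell. This order turned round under size factors (0.9548 and 0.9228), quantile normalization (0.9244 and 0.914) and the first GC and length correction (0.923 and 0.9168). Positions under 0.5 were found for 24.2% and 21.5% of these genes, and positions over 1 for 38.9% and 49.6%. Choosing genes by the HTL change shrinks such a position somewhat towards 0. Against control, 1013 of the genes that rose and 426 of those that fell were not called in betaine plus HTL cells.

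The 13 mitochondrial protein-coding transcripts did not pass as a list in any comparison (camera adjusted p = 0.666, 0.72 and 0.597). Within it CYTB, a subunit of respiratory complex III (mitochondrial chromosome, 14145 to 15288), rose from 2842 ± 79.96 to 4346 ± 86.2 FPKM with HTL and stood at 4258 ± 306 FPKM with betaine plus HTL. ND5 rose from 903 to 1127 FPKM, ND4 from 665 to 755 FPKM and COX1 from 5922 to 6395 FPKM with HTL, while ND1 was at 3909 and 3666 FPKM (limma adjusted p = 0.0801).

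**Figure D5:**
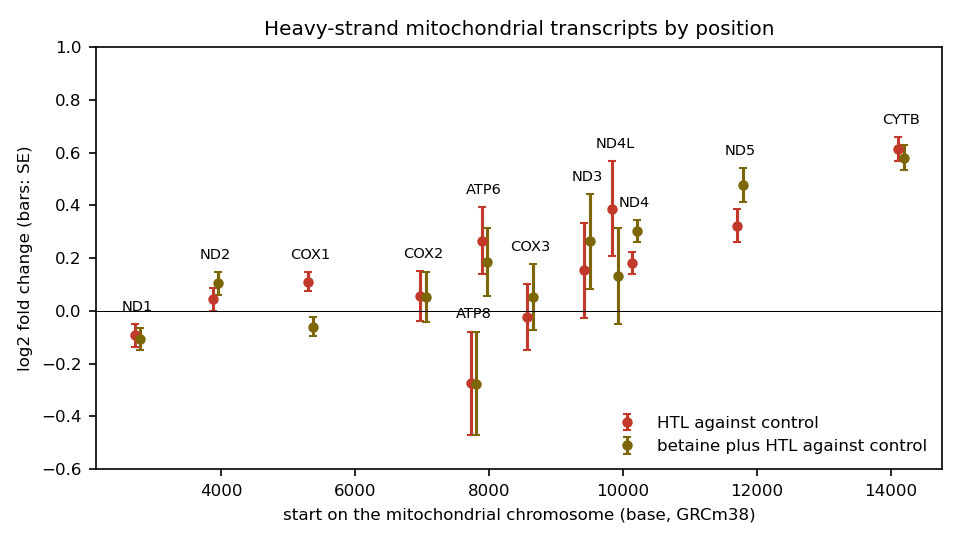
Log2 fold change (y axis, error bars SE) of 12 heavy-strand mitochondrial transcripts by start position in bases (x axis), for HTL against control and betaine plus HTL against control. CYTB, at the far end, lies at 0.61 and 0.58.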

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

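The voom fit and both GC and length corrections were chosen after the data were seen, and the second correction, which keeps each library's mean, after the share of rises under the first was known. Counts of called genes moved by less than 1.5 times under every setting except one. Asking for a log2 fold change of at least 1 as well left 50 genes in HTL against control, 6 in betaine plus HTL against HTL and 89 in betaine plus HTL against control, because most changes were small. Leaving out 1 library gave 5962 to 6788, 3057 to 3851 and 6435 to 6939 genes, 38 to 43 called lists (43 with all libraries), 1131 to 1395 opposite changes and 739 to 984 changes in the same direction. Voom on recovered reads called 6930, 4300 and 7143 genes.

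The covariance of the fold changes, -0.0044, became -0.0098 with a pseudocount of 0.1, -0.0017 with a pseudocount of 5, -0.0033 without the filter, -0.003 with the filter at 5, -0.0068 with TPM, -0.0114 with voom and -0.005 with either GC and length correction. The correlation, -0.1021, became -0.1382, -0.0799, -0.136, -0.0736, -0.1197, -0.1442 and -0.1166 in this order. Leaving out 1 library gave -0.0054 to -0.0042 and -0.1211 to -0.0942. The value without an effect was simulated for the settings of the report alone, so these values have no such reference.

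The position of genes that rose (0.864) became 0.9244 with quantile normalization, 0.8986 with TPM, 0.9548 with size factors, 0.923 with the first GC correction and 0.9206 when chosen without HTL replicate 1 and read from it. That of genes that fell (0.993) became 0.9811 without the filter, 0.914, 0.9527 and 0.9228 under these scalings, 0.9168 with the first GC correction, and 1.0177 and 1.0175 when chosen without HTL replicates 2 and 3. Leaving out 1 library gave 0.8459 to 0.8809 and 0.9795 to 1.004. So whether genes that rose lie nearer control than genes that fell depends on the scaling, and the cause was not tested.

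The replicate numbers do not pair the libraries: deviations of same-numbered libraries correlated at -0.07 to 0.06, and 1 of 9 libraries correlated best with its own number. With the number as a block, 6532, 3690 and 6920 genes were called. Over the 21 settings run for lists and named genes (not the 6 libraries alone or the added fold change), 1892 list results kept their side of the threshold, 56 fell short and 5 newly passed. For named genes these were 4047, 31 and 19, and none reversed. Scaling moved the median of all genes by less than 0.1 on the log2 scale. DESeq2 and edgeR on raw counts were planned for a table with counts and were not run. In the simulation, where few genes changed, 6% of 1.1-fold changes were recovered; the threshold on adjusted p is less strict where many genes pass, so that share does not carry over to these comparisons.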

Other observations

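The GO term tests, the mitochondrial range and position tests, the reading of genes by their distance from the median or from 0, the reading within 5 groups of genes by GC content or length, the GC correction that keeps library means, and the reading of LXR targets against the spread of the members were chosen after results were seen. GO terms of the deposited annotation with 15 to 200 tested genes were run with camera, 1915 in each comparison. At the preset correlation 63, 26 and 65 terms passed in HTL against control, betaine plus HTL against HTL and betaine plus HTL against control. With an estimated correlation 0 passed in each, where 99, 113 and 97 had an unadjusted p under 0.05. Cholesterol biosynthetic process, with 22 of 26 genes falling with HTL, went from an unadjusted camera p of 1.68e-15 to 0.000111 (adjusted p = 0.106). With few residual degrees of freedom this form could thus hardly pass a term among 1915. Its failures do not tell the terms apart. Proteasome complex genes fell in 34 and rose in 7 of 56 with HTL (median -0.13, adjusted p = 1.04e-06, and adjusted p = 0.826 with an estimated correlation), and fell in 41 and rose in 7 in betaine plus HTL against control (median -0.18, adjusted p = 1.13e-06, and adjusted p = 0.848 with an estimated correlation). Psmd11, a lid subunit, went from 87.2 to 72.2 FPKM with HTL. Genes of the tricarboxylic acid cycle fell in 17 and rose in 4 of 29 with HTL (adjusted p = 0.00136, and adjusted p = 0.916 with an estimated correlation), with citrate synthase, Cs, from 201 to 163 FPKM.

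In betaine plus HTL against HTL, spliceosomal complex genes fell in 56 and rose in 6 of 160 (median -0.07, adjusted p = 0.0333, and adjusted p = 0.805 with an estimated correlation). Genes for charging tRNAs rose in 13 and fell in 2 of 33 (median 0.06, adjusted p = 0.0175, and adjusted p = 0.805 with an estimated correlation).

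Cholesterol synthesis genes fell with HTL and fell further with the pretreatment. A trend with GC content and length between libraries is argued against as the whole cause, since after correction the median was still -0.578 in the comparison where it was closer to 0. A hypothesis written before its test was that sterols accumulate and are sensed by the receptor LXR, whose targets should then rise. Of 6 measured targets outside the lists, 4 fell and 1 rose with HTL (median -0.194, SD over members 0.29), and 3 fell and 0 rose with the pretreatment (median -0.119, SD 0.27); in betaine plus HTL against control 4 fell and 1 rose (median -0.359, SD 0.36). Limma's camera gave the targets an unadjusted p of 0.0753, 0.127 and 0.0454 in this order, each downward, so the rise that was asked for was not seen. The outcome written beforehand against the hypothesis, a median at or under 0 with HTL and with the pretreatment, was met. By a reading added afterwards, the medians lie within the spread of so few members, so the hypothesis stays open. A direct loss of SREBP2 activity, which was not tested, stays open too.

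CYTB rose in both HTL groups. For a different yield of mitochondrial RNA as a whole, the changes ranged over 0.886 in the 13 transcripts (0.705 in the 7 with at least 100 FPKM). CYTB, picked for its rise, sets the upper end of both ranges, so they cannot decide. Without CYTB the abundant transcripts still ran from ND1 at -0.093 ± 0.043 SE to ND5 at 0.323 ± 0.064 SE. That difference argues against an equal change of all as the whole cause. A GC and length trend is argued against by a CYTB change of 0.579 after correction. A hypothesis is that the change follows the place along the heavy-strand transcript: across 12 transcripts, which are not independent replicates, Spearman's rho was 0.77 (permutation p = 0.005, adjusted p = 0.0067 over 4 relations) and Pearson's r 0.71 (permutation p = 0.0096) in HTL against control. The transcripts between COX1 and ND4 were far lower than these 2, from ND4L at 10.1 to COX2 at 116 FPKM in control. Their changes had an SE of 0.094 to 0.195, so they are less certain. COX2, counted among the abundant ones, was at 116 FPKM beside 5922 FPKM for COX1. Reads of these low transcripts may have been dropped if they fit near-identical copies elsewhere, which was not checked. Rank correlations that include them carry that uncertainty. The rank correlation was 0.96 over the 7 abundant transcripts (exact permutation p = 0.0028, adjusted p = 0.0056), 0.82 in betaine plus HTL against control (permutation p = 0.0019, adjusted p = 0.0056) and 0.27 in betaine plus HTL against HTL (permutation p = 0.39, adjusted p = 0.39). Without CYTB and ND1, the farthest in position, the rank correlation was 0.65 (permutation p = 0.0497) over the other 10 and 0.9 over the other 5 abundant transcripts (exact permutation p = 0.0833), each with an adjusted p of 0.0828 or more over 5 such readings. Without CYTB alone it was 0.7 over 11 transcripts (permutation p = 0.0199, adjusted p = 0.0512). In betaine plus HTL against control it was 0.73 without CYTB and ND1 (permutation p = 0.0205, adjusted p = 0.0512). Pearson's r without these 2 was 0.46 over the 10 in HTL against control (permutation p = 0.18). So Pearson's r rests on them, for the ranks this stays open, and position may matter or something particular to CYTB.

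More genes rose than fell with HTL (66.1%), with 68.3% among called genes at least 0.3 (log2) from 0 and 65% among those nearer. A GC trend is argued against, since the share was 64.6% to 67.1% in each of 5 equal groups of genes by GC content and the fold change correlated with GC content at 0.003 across genes, which are not independent replicates. A part for length, as inferred with the reads, stays open. The share was 56.5% in the group of 5 with the shortest genes (95% Wilson interval 53.6% to 59.3%, counting error alone) and 70.3% in that with the longest. The fold change correlated with log2 length at 0.052 in HTL against control. That correlation was larger in the other comparisons, at 0.166 in betaine plus HTL against HTL and 0.142 in betaine plus HTL against control. Scaling stays open too, since the tests gave 52.2% under quantile normalization, 50.6% after the first GC and length correction and 46% above the median among genes at least 0.3 from it, all fixed near an even split by centring, and 65.9% with library means kept, which holds the offset. A broad rise in many genes may give the same values, and no outside standard was analysed here to separate them.

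With 10 splits of the 6 libraries in each comparison, no share under 0.05 can be reached. The real split called 6639, 3871 and 6981 genes, the highest other split called 0 in each, and 1 split of 10, the real one, gave as many genes.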
